A study of Oryzias latipes with 12 samples.

How the data were processed

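Polyadenylated RNA was sequenced as strand-specific paired-end libraries from 12 medaka brain samples holding ventral telencephalon, hypothalamus and pituitary, in 4 groups of 3 libraries (wild type and phod1 knockout, each under short days or 12 days after transfer to long days). The authors' processing notes name STAR 2.7.9a and RSEM 1.3.1 without stating the part each played. The genome build and annotation release are not given in the sources used here, so no gene coordinates are printed. The values deposited by the authors are TPM (length-scaled transcript abundances) per gene and library, with each column summing to 1000000 within rounding and values kept to 2 decimals. All 26663 genes carry an NCBI Gene ID that matched a gene of the reference for the assembly ASM223467v1, which gave the symbols and the order of genes along chromosomes. No read counts were used, so the depth of each library is unknown and no counting error can be given. The number of libraries and their spread set the precision. Reads shared by near-identical gene copies are divided by the quantification, which leaves the values of such copies uncertain.

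Genes with a TPM of at least 1 in at least 3 libraries were tested, 18218 in all. Values entered as log2(TPM + 1), without further scaling between libraries, into 1 limma fit (version 3.58.1 in R 4.3.3) with 4 group means and a mean-variance trend in the prior variance. The pseudocount of 1 makes the changes of genes with few TPM smaller than their ratios. There were 7 contrasts: long against short days in wild type, in the knockout and over both, knockout against wild type under short days, under long days and over both, and the interaction. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Called genes are those said to rise, fall or pass. The fit was tested on simulated data, drawn from a normal distribution around each gene's mean over the groups with the spread fitted to the 12 libraries. In the wild-type photoperiod comparison of 1 such data set, 75 of 100 genes changed by 1 on the log2 scale and 93 of 100 changed by 2 were called in the right direction. The same run gave 15 false calls, and a run with nothing changed gave 0 calls by limma.

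Gene lists for pathways, cell types and RNA quality, 37 in all, were fixed together with the contrasts, the tests and most of the other settings before the data were examined. The 27 with at least 5 tested members were tested by camera, from limma, with a preset correlation between genes of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. Camera compares the members of a list with the other tested genes, so a list median near 0 can go with a small p. Members passing after adjustment over the list alone were counted as well. Some genes belong to more than 1 list.

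Genes were named by a rule. For each contrast these were the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 1 TPM in the higher group and no overlap between the groups' libraries. Added to them were up to 4 called members of each list by smallest adjusted p, at most 2 rising and 2 falling genes without a symbol, and a set of reproductive, thyroid, clock and opsin genes named whatever their result where tested. Of that set tshb, gh1, kiss1, kiss2, opn5, eya3, cry1a and nr1d1 matched no symbol or synonym, and prl was below the filter. Where no gene with a symbol passed, the 3 rising and 3 falling genes with the smallest p were named as not passing.

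Alternatives changed 1 choice at a time. They were a pseudocount of 0.1, a filter of a TPM above 0 in any library, a filter of at least 5 TPM in at least 3 libraries, median-ratio scaling, removal of the 20 most abundant genes, no trend in the prior variance, limma array weights, a fit to the 2 compared groups alone, the number in the sample titles as a replicate block within photoperiod, and leaving out each library of the compared groups in turn. Leaving short-day wild-type replicate 3 out of fits for comparisons it is not part of was added later. The clustering of calls along chromosomes was compared with 100000 random placements of as many calls over the tested genes. It was repeated, after the result was seen, for the 121 and the 117 genes with the smallest p in each pooled contrast. Labels of the samples were also regrouped, over all 10 splits for groups of 3 and over 100 of 200 possible splits for contrasts of all groups. No sample was left out of the main results.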

Results

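RNA was sequenced from 12 brain samples of medaka (Oryzias latipes), each holding ventral telencephalon, hypothalamus and pituitary. The samples formed 4 groups of 3 libraries: wild type and phod1 knockout, each taken at hour 12 either under short days or 12 days after a move to long days. The table gave transcript levels as TPM for 26663 genes, and 18218 genes with a TPM of at least 1 in at least 3 libraries were tested, 9446 of them with a symbol other than a LOC number. TPM keeps no read counts, so the depth behind each value is unknown. Pearson correlations of log2(TPM + 1) across genes ran from 0.971 to 0.980 within groups and from 0.957 to 0.979 between groups. The first principal component held 19.4% of the variance and placed all wild-type libraries below 0 and all knockout libraries above 0. The second component held 13.9%. The knocked-out gene could not be checked in the libraries, because neither phod1 nor the series' short name pd1 matched a symbol or synonym of the table's genes. The labels do not state that each library came from a separate fish, so the p-values below measure only the spread between samples.

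Interferon and antiviral genes set 1 library apart. In short-day wild-type replicate 3, rsad2, an antiviral interferon-induced gene, stood at 287 TPM, against 6.3 TPM or less in each of the other 11 libraries. In the same library dhx58, a RIG-I-like receptor, stood at 85.2 TPM, irf9, a transcription factor of interferon signalling, at 34.3 TPM, and cmpk2 at 64.1 TPM. Over the 8 tested interferon and antiviral genes, this library lay a median of 2.82 log2 units above the mean of the other 2 libraries of its group. The same median ran from -1.5 to 0.43 in the other 11 libraries, each against the rest of its own group. The lowest values, -1.21 and -1.50, were those of short-day wild-type replicates 1 and 2, which were compared with a mean that includes replicate 3. In the knockout and long-day libraries the median ran from -0.20 to 0.43. Short-day wild-type replicate 3 also held fshb at 31.4 TPM, against 122 and 115 TPM in the other short-day wild-type libraries.

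**Figure D1:**
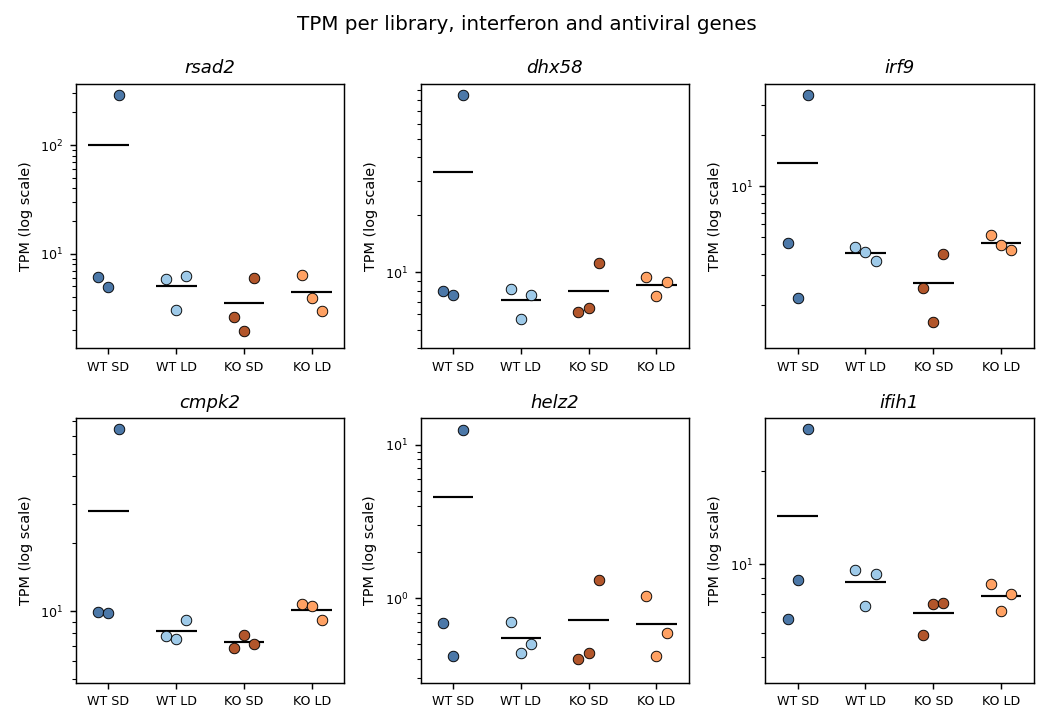
TPM on a log scale for 6 interferon and antiviral genes in each library (points) with the group mean (line), in wild type (WT) and phod1 knockout (KO) under short days (SD) and long days (LD), n = 3 libraries per group. One short-day wild-type library lies above every other library in all 6 panels, with rsad2 at 287 TPM.

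The wild-type comparison shows which genes differed between short days and 12 days of long days. The short-day libraries were taken before the move, and no short-day group was sampled 12 days later. In every photoperiod comparison here, day length therefore cannot be told apart from elapsed time, age or the move itself. The 3 gonadotropin subunit genes rose (values are mean ± SD in TPM, n = 3 libraries per group). The FSH β subunit gene fshb (gene 105356452) rose from 89.6 ± 50.5 to 988 ± 93.0, a change in log2(TPM + 1) of 3.67 (SE 0.38, adjusted p = 0.00497). The LH β subunit gene lhb (gene 100125483) rose from 46.7 ± 10.4 to 242 ± 28.5 (2.36, SE 0.26, adjusted p = 0.00588), and cga (gene 100144350), the α subunit shared by the glycoprotein hormones, rose from 354 ± 85.2 to 1446 ± 252 (2.04, SE 0.26, adjusted p = 0.0103). The brain aromatase gene cyp19b (gene 100125815), which in fish is expressed in radial glia, rose from 240.3 ± 49.4 to 778 ± 115 (1.70, SE 0.17, adjusted p = 0.00497). The A subunit of coagulation factor XIII, f13a1, rose from 7.09 ± 4.98 to 61.1 ± 4.11 (adjusted p = 0.0169). Smaller rises were those of gltp, a glycolipid transfer protein, from 0.783 ± 0.335 to 3.04 ± 0.547, and of the cAMP phosphodiesterase pde7b from 2.55 ± 0.179 to 5.26 ± 0.118. The F-box gene fbxo25 rose from 22.4 ± 1.18 to 33.5 ± 2.87, and rnaseh2b, a subunit of RNase H2, from 22.5 ± 1.3 to 32.9 ± 0.615. Of genes without a symbol, LOC101174341 rose from 15.8 ± 1.19 to 33.5 ± 2.48 and LOC101161642 from 13.5 ± 0.852 to 22.2 ± 1.06.

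Under long days 23 genes fell in wild type. The ferrochelatase gene fech, which inserts iron in the last step of haem synthesis, fell from 80.9 ± 1.87 to 47.3 ± 3.63 (-0.76, SE 0.09, adjusted p = 0.00690), and flvcr1, a transporter described for haem export, from 61.9 ± 5.08 to 37.9 ± 1.11 (adjusted p = 0.00588). The retinoic acid-degrading enzyme cyp26b1 showed the largest fall among genes with a symbol, from 8.23 ± 1.5 to 1.44 ± 0.0721 (-1.91, SE 0.24, adjusted p = 0.0103). The leptin gene lep-b fell from 3.28 ± 0.396 to 1.02 ± 0.179. The J-domain co-chaperone genes dnajc15 and dnajc25 fell from 74.0 ± 10.6 to 43.4 ± 1.60 and from 32.0 ± 1.38 to 19.1 ± 0.925. The mitochondrial arginase gene arg2 fell from 93.3 ± 10.0 to 56.7 ± 7.63, ccdc51 from 22.4 ± 1.65 to 13.7 ± 1.39, and gcat, of threonine breakdown, from 29.1 ± 2.29 to 19.0 ± 0.486. The ceramide-1-phosphate transfer protein cptp fell from 33.8 ± 2.78 to 21.2 ± 1.00. LOC101164777 fell from 7.36 ± 2.12 to 1.86 ± 0.538, and LOC101165212 from 4.76 ± 1.93 to a level listed at 0 in all 3 long-day libraries.

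Across all tested genes, 35 passed in wild type, 12 higher and 23 lower under long days, and 12 of the 35 changed by at least 1 on the log2 scale. With median-ratio scaling of the libraries 27 passed, 14 higher and 13 lower, and with array weights 292 passed, 70 higher and 222 lower. In the main fit an unadjusted p under 0.05 was reached by 2117 genes. Each gene named above by the size of its change was required to have every library of 1 group above every library of the other. This separation is therefore no separate support, and chance gives it with a probability of 10% for 3 against 3. Calls for fshb, lhb, cyp19b, fech, flvcr1 and LOC101174341 held with each library left out in turn. A fit to the 2 wild-type groups alone kept 1 of the 35 calls, that of lhb among the genes just named (adjusted p = 0.0365, with 0.00245 to 0.0365 over all alternatives), and adjusted p, there the highest over each gene's alternatives, was 0.115 for fshb, 0.0727 for flvcr1 and 0.0515 for cyp19b, fech and LOC101174341. Those of cga and cyp26b1 were lost without short-day replicate 1, long-day replicate 13 or long-day replicate 15, those of dnajc15 and dnajc25 without long-day replicate 15, and that of LOC101164777 without short-day replicate 2 or long-day replicate 13. Every other named gene was lost without 4 or more of the 6 libraries. The count was 13, 11 and 23 without short-day replicates 1, 2 and 3, and 10 without either long-day replicate 13 or long-day replicate 15. Of the thyroid and clock genes fixed in advance, dio2 stood at 5.43 ± 2.2 and 8.41 ± 1.76 (adjusted p = 0.596), dio3 at 14 ± 1.07 and 10.2 ± 1.25 (adjusted p = 0.289) and per2 at 32.3 ± 0.130 and 23.6 ± 3.66 (adjusted p = 0.213) under short and long days. The gonadotropin-releasing hormone gene gnrh1 stood at 26.8 ± 8.42 and 43.4 ± 4.20 (adjusted p = 0.138), and passed without short-day replicate 1 (adjusted p = 0.0363, with 0.0363 to 0.336 over all alternatives).

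Of 27 gene lists tested by camera in wild type, 8 had an adjusted p under 0.05 with the preset correlation of 0.01, and 0 with an estimated correlation, where the smallest adjusted p was 0.0773. In the gonadotropic axis list, 4 of 14 members rose (fshb, lhb, cga, cyp19b), 0 fell and 10 did not pass, and 6 rose when adjusted over the list alone, gnrh1 and the progesterone receptor gene pgr with them (adjusted p = 3.26e-07 by camera, adjusted p = 0.0773 with an estimated correlation). The pituitary hormone list shares fshb, lhb and cga with it, and these were the 3 of 8 members that rose, over all genes and adjusted over the list alone (adjusted p = 0.000763, adjusted p = 0.188 with an estimated correlation). In the list of radial glia and astroglia, which shares cyp19b with the gonadotropic axis, that gene alone of 6 members rose, and the glial calcium-binding protein gene s100b joined it when adjusted over the list alone (adjusted p = 0.00775, adjusted p = 0.167 with an estimated correlation). Of 34 cell cycle genes 27 were higher under long days, with a median of 0.19. No member passed over all genes, and 2 rose when adjusted over the list alone, the mitotic kinase cdk1 (14.5 ± 0.577 and 20.1 ± 3.29) and the replicative helicase subunit mcm7 (13.9 ± 1.40 and 20.6 ± 1.71; adjusted p = 4.48e-07, adjusted p = 0.188 with an estimated correlation).

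In the other wild-type lists with a call no member passed over all genes or over the list alone. Ribosomal protein genes were higher under long days in 65 of 67 members, with a median of 0.13 (adjusted p = 2.97e-16, adjusted p = 0.717 with an estimated correlation). Oxidative phosphorylation genes were higher in 33 of 49 members, with a median of 0.04, or 0.0882 with median-ratio scaling (adjusted p = 0.00702, adjusted p = 0.717 with an estimated correlation). That call was lost without short-day replicate 2 (adjusted p = 0.115) or long-day replicate 13 (adjusted p = 0.661). Immediate early genes were lower in all 12 members, with a median of -0.24 (adjusted p = 0.0292, adjusted p = 0.717 with an estimated correlation). That call was lost without short-day replicate 1 (adjusted p = 0.0873), long-day replicate 14 (adjusted p = 0.0960) or long-day replicate 15 (adjusted p = 0.0801). Interferon and antiviral genes were lower under long days in all 8 members, with a median of -0.91 (adjusted p = 0.0292, adjusted p = 0.717 with an estimated correlation). Without short-day replicate 3, the library with rsad2 at 287 TPM, the adjusted p was 0.937, and without long-day replicate 14 it was 0.226.

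**Figure D2:**
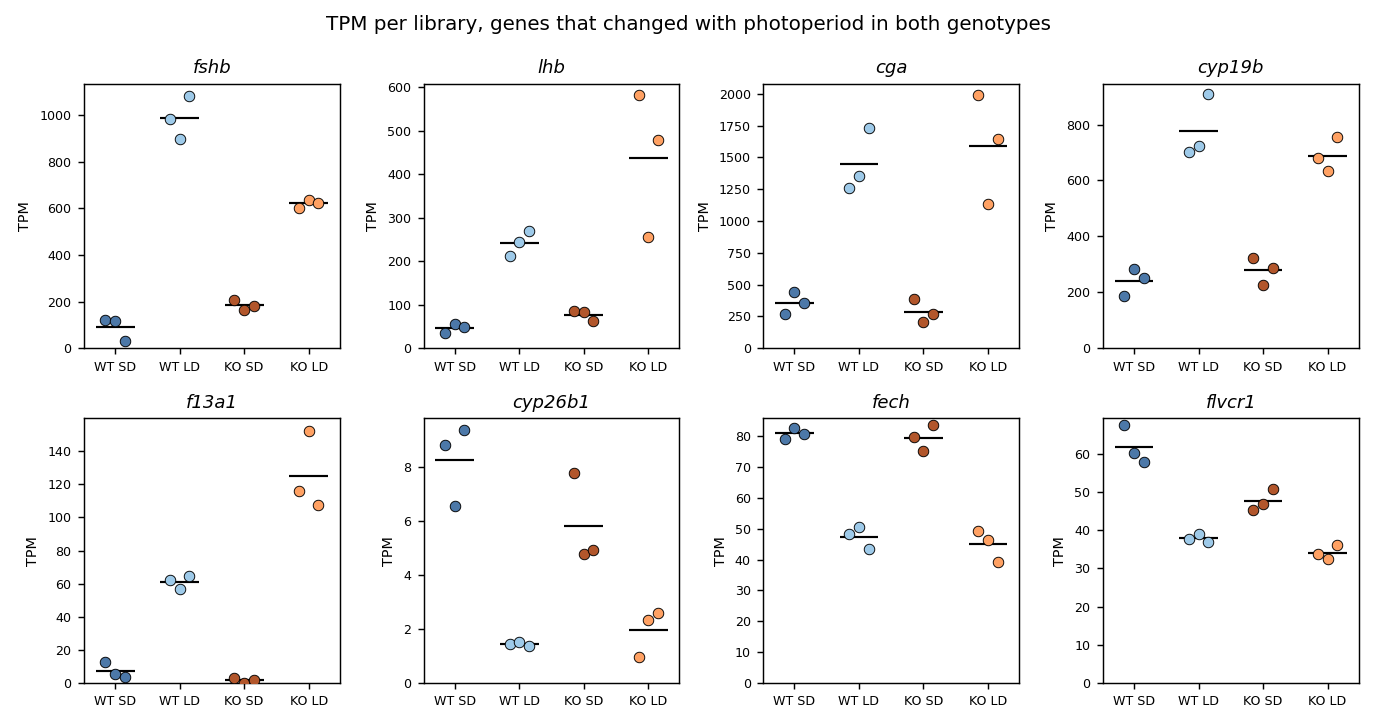
TPM of 8 genes that passed in both photoperiod comparisons, in each library (points) with the group mean (line), in wild type (WT) and phod1 knockout (KO) under short days (SD) and long days (LD), n = 3 libraries per group. The fshb mean was 89.6 TPM in WT SD and 988 TPM in WT LD, and the cyp26b1 mean was 8.23 and 1.44 TPM.

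The knockout comparison asks the same question in fish without phod1. In the knockout f13a1 rose from 1.56 ± 1.41 to 125 ± 23.7 (5.78, SE 0.44, adjusted p = 0.000370). The gonadotropin subunit genes cga and lhb rose from 285 ± 94.0 to 1590.0 ± 433 (2.49, SE 0.26, adjusted p = 0.00171) and from 76.8 ± 12.5 to 439 ± 167 (2.43, SE 0.26, adjusted p = 0.00171). The third subunit, fshb, rose from 184 ± 21.4 to 621 ± 16.9 (1.76, SE 0.38, adjusted p = 0.0464), a call lost without any 1 of the 6 knockout libraries, with adjusted p up to 0.144. Its knockout libraries stood at 163 to 206 TPM under short days and at 602 to 635 TPM under long days. The SE comes from the spread shared by all 4 groups. That spread includes short-day wild-type replicate 3, at 31.4 TPM against 122 and 115 TPM in the rest of its group. Brain aromatase cyp19b rose from 278 ± 49.2 to 689 ± 61.2 (1.32, SE 0.17, adjusted p = 0.00419). Other rises were those of dapl1, from 23.3 ± 17.3 to 89.1 ± 20.3, and of klhl24, a kelch-repeat ubiquitin ligase adaptor, from 3.25 ± 0.0289 to 10.2 ± 2.93. The serine palmitoyltransferase subunit sptlc3 rose from 9.43 ± 3.47 to 23.0 ± 3.83, gltp from 1.11 ± 0.176 to 4.03 ± 0.825, and gpr143, a melanosomal receptor, from 2.67 ± 0.643 to 7.11 ± 0.727. LOC110015663 rose from 0.507 ± 0.238 to 15 ± 6.27 and LOC101156361 from 0.293 ± 0.508 to 9.35 ± 2.73.

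Among the knockout falls were again fech, from 79.4 ± 4.25 to 44.9 ± 5.20 (-0.81, SE 0.09, adjusted p = 0.00171), and cyp26b1, from 5.81 ± 1.70 to 1.96 ± 0.872 (-1.22, SE 0.24, adjusted p = 0.0357). The mitochondrial ribosomal protein gene mrpl49 fell from 67.0 ± 13.5 to 27.0 ± 3.73, and odc1, which makes the polyamine putrescine, from 65.6 ± 6.06 to 38.1 ± 4.99. The PGC-1-related coactivator gene pprc1 fell from 10.9 ± 1.2 to 5.67 ± 0.840, and pfkfb3, which makes an activator of glycolysis, from 39.1 ± 4.13 to 21.3 ± 3.30. The procollagen C-endopeptidase enhancer pcolce2 fell from 14.4 ± 3.19 to 7.23 ± 0.363 and tmem130 from 6.42 ± 2.36 to 1.2 ± 1.06. The gene c23h12orf45 fell from 18.5 ± 1.55 to 8.56 ± 0.756, and s100p from 2.33 ± 1.34 to a level listed at 0 in all 3 long-day libraries. LOC101155766 fell from 14.6 ± 2.81 to 1.02 ± 0.496 and LOC101170847 from 5.4 ± 1.60 to 0.213 ± 0.370.

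In the knockout 321 genes passed, 202 higher and 119 lower under long days, and 2898 reached an unadjusted p under 0.05. With median-ratio scaling 374 passed, 192 higher and 182 lower. A fit to the 2 knockout groups alone gave 61. Calls for f13a1, cga, lhb, cyp19b, gpr143, odc1, fech, c23h12orf45, mrpl49 and all 4 named LOC genes held with each knockout library left out in turn, and every other named gene lost its call without at least 1 of them. In the fit to the knockout groups alone the calls of gpr143 and odc1 were lost (adjusted p = 0.0603 and 0.0521). The count was 191, 122 and 111 without short-day replicates 1, 3 and 4, and 86 and 81 without long-day replicates 13 and 14. Leaving short-day wild-type replicate 3 out of the shared estimate of the spread, an alternative chosen after the data were seen, gave 212. The always-reported genes dio2 (5.15 ± 3.38 and 8.00 ± 0.316), dio3 (10.3 ± 0.905 and 9.89 ± 2.1), per2 (32.4 ± 3.75 and 28.6 ± 4.35) and gnrh1 (33.0 ± 2.58 and 36.9 ± 3.20) had adjusted p of 0.401, 0.873, 0.554 and 0.713.

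Of the 27 lists, 8 had a call in the knockout with the preset correlation and 0 with an estimated one. Cell cycle genes were higher under long days in 25 of 34 members. The 3 that rose were mcm7, from 13 ± 1.01 to 21.3 ± 1.92, cdk1, from 14.5 ± 0.707 to 22.0 ± 0.416, and tpx2, a spindle assembly factor, from 2.48 ± 0.237 to 4.81 ± 0.551. Within the list 7 rose when adjusted over the list alone (adjusted p = 0.00856 by camera, adjusted p = 0.492 with an estimated correlation). The list's call was lost without short-day replicate 1 (adjusted p = 0.0706) or long-day replicate 13 (adjusted p = 0.0796). In the gonadotropic axis 4 of 14 members rose, over all genes and adjusted over the list alone (adjusted p = 0.0178, adjusted p = 0.492 with an estimated correlation). Without long-day replicate 16 the adjusted p was 0.0989. Of 8 pituitary hormone genes 3 rose by either count, the same fshb, lhb and cga (adjusted p = 0.00850, adjusted p = 0.492 with an estimated correlation). Outside the called lists, s100b rose from 702 ± 53.5 to 975 ± 137 (adjusted p = 0.0397) and the catalase gene cat from 65.6 ± 5.84 to 98.6 ± 13.7 (adjusted p = 0.0464).

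Proteasome, cholesterol and stress gene lists were lower under long days in the knockout. Proteasome genes were lower in 26 of 31 members, with a median of -0.13, and 1 fell by either count, psmd6 from 127 ± 2.90 to 102 ± 3.28 (adjusted p = 1.68e-06 by camera, adjusted p = 0.492 with an estimated correlation). Cholesterol synthesis genes were lower in 16 of 21 members, with a median of -0.23. In that list 1 fell over all genes, dhcr7, the enzyme of the last step to cholesterol, from 36.1 ± 3.98 to 24.7 ± 1.43, and 6 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.492 with an estimated correlation). Immediate early genes were lower in 11 of 12 members, and 1 fell when adjusted over the list alone, npas4, from 90.4 ± 35.8 to 44.7 ± 14.4 (adjusted p = 0.00294, adjusted p = 0.492 with an estimated correlation). That list's adjusted p was 0.256 without short-day replicate 4 and 0.0553 without long-day replicate 14. Heat shock and ER stress genes were lower in 13 of 19 members, of which 2 fell when adjusted over the list alone, the mitochondrial chaperonin hspd1 and the glutathione-degrading chac1 (adjusted p = 0.00890, adjusted p = 0.492 with an estimated correlation). Without long-day replicate 14 the adjusted p was 0.0924. Ribosomal protein genes, higher under long days in wild type, were lower in 55 of 67 members in the knockout, with a median of -0.05 (-0.0813 with median-ratio scaling) and no member passing by either count (adjusted p = 0.0178, adjusted p = 0.912 with an estimated correlation). That call was lost without short-day replicate 1 (adjusted p = 0.0686), short-day replicate 4 (adjusted p = 0.0827) or long-day replicate 13 (adjusted p = 0.831).

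Both genotypes shared 20 photoperiod calls. The 10 that rose in both were fshb, lhb, cga, cyp19b, f13a1, gltp, pde7b, fbxo25, LOC101161642 and LOC101174341, against 0.133 expected for independent lists of this size, and the 10 that fell in both, against 0.150 expected, included fech, flvcr1, cyp26b1 and dnajc15. The 2 comparisons share each gene's estimate of the spread, so their lists are not independent and the expected numbers are no clean level for chance. No gene passed in opposite directions. Of the 35 wild-type calls 32 had the same sign in the knockout, and of the 321 knockout calls 271 had the same sign in wild type. Across the 18218 genes, which are not independent replicates, the changes in the 2 genotypes correlated with Pearson's r = 0.179 and Spearman's rho = 0.276.

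**Figure D3:**
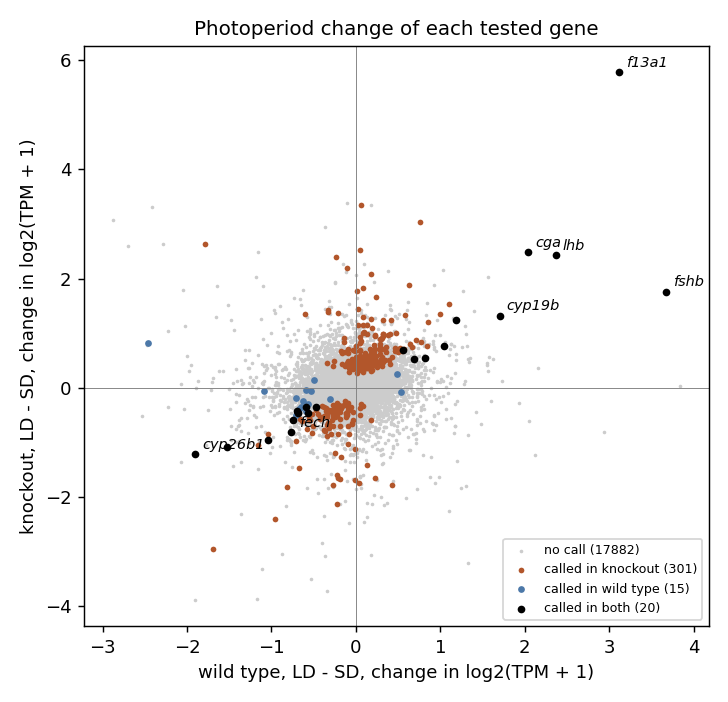
Change in log2(TPM + 1) from short days (SD) to long days (LD) for each tested gene (points), in wild type on the horizontal axis and in the knockout on the vertical axis, n = 3 libraries per group, with colours for genes called in neither (17882), in wild type only (15), in the knockout only (301) or in both (20). The labelled gonadotropin genes and cyp19b lie in the upper right, and fech and cyp26b1 in the lower left.

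The test of the difference between the photoperiod responses of the genotypes, the interaction, passed for 1 gene. LOC110015663 stood at 0.390 ± 0.200 and 0.447 ± 0.229 in wild type and at 0.507 ± 0.238 and 15 ± 6.27 in the knockout under short and long days (difference 3.29, SE 0.37, adjusted p = 0.0330). An unadjusted p under 0.05 was reached by 1444 genes. The genes with a symbol and the smallest p did not pass. Of these, asic4, an acid-sensing channel, and the deacetylase hdac11 had positive differences, knockout minus wild type (0.92 and 0.76, adjusted p = 0.132 for each). So did gpat3, an enzyme of triglyceride synthesis (0.63, adjusted p = 0.124). Negative differences included those of c23h12orf45 (-0.93, adjusted p = 0.130) and the ribosome maturation factor sbds (-0.62, adjusted p = 0.130). The sign alone does not show which genotype changed more. Mean TPM of asic4 went from 28.0 to 29.7 in wild type and from 26.4 to 54.3 in the knockout. That of gpat3 went from 46.8 to 32.9 and from 38.2 to 41.9, and that of sbds from 146 to 141 and from 150 to 94.2. For fshb the knockout response minus that of wild type was -1.91 (SE 0.54, adjusted p = 0.413). Without short-day wild-type replicate 3, where fshb stood at 31.4 TPM, the value was -1.29 and passed (adjusted p = 0.0177), as did sbds at -0.70 (adjusted p = 0.0440), and with array weights gpat3 passed (adjusted p = 0.0486). Over all alternatives the adjusted p of each of these 3 genes ran up to 0.666. For lhb the difference was 0.07 (SE 0.37, adjusted p = 0.976). For cga, cyp19b, gnrh1, dio2, dio3 and per2 the adjusted p ran from 0.606 to 0.969. The count was 0 without short-day wild-type replicate 1 or 2 or any 1 of the long-day wild-type libraries 13, 14 and 15. It was 4 without short-day wild-type replicate 3, 6, 2 and 5 without short-day knockout replicates 1, 3 and 4, and 6, 2 and 3 without long-day knockout replicates 13, 14 and 16.

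Of the lists, 3 passed the interaction test with the preset correlation and 0 with an estimated one, and no member of them passed over all genes or over the list alone. For ribosomal protein genes the signed difference, knockout minus wild type, was below 0 in 64 of 67 members, with a median of -0.18 (adjusted p = 1.41e-19 by camera, adjusted p = 0.697 with an estimated correlation). Their median change under long days was 0.13 in wild type and -0.05 in the knockout. For cholesterol synthesis genes the difference was below 0 in 15 of 21 members, with a median of -0.24 (adjusted p = 0.00238, adjusted p = 0.697 with an estimated correlation). Here the median change was -0.08 in wild type and -0.23 in the knockout, the larger fall. The cholesterol call was lost without short-day wild-type replicate 3, the library with high interferon genes (adjusted p = 0.126), or short-day knockout replicate 3 (adjusted p = 0.123). For proteasome genes the difference was below 0 in 21 of 31 members, with a median of -0.05, or -0.128 with median-ratio scaling (adjusted p = 0.00457, adjusted p = 0.697 with an estimated correlation). Their median change was -0.07 in wild type and -0.13 in the knockout, again the larger fall. The proteasome call was lost without long-day knockout replicate 14 (adjusted p = 0.0705).

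Averaged over both genotypes, with 6 libraries against 6, f13a1 rose under long days by 4.45 on the log2 scale (SE 0.31, adjusted p = 0.000201), fshb by 2.71 (SE 0.27, adjusted p = 0.000831). Under the same test lhb rose by 2.4 (SE 0.19, adjusted p = 0.000202), cga by 2.26 (SE 0.19, adjusted p = 0.000246) and cyp19b by 1.51 (SE 0.12, adjusted p = 0.000202). Further rises were those of klhl24 (1.18), gltp (1.21), the kinase map3k19 (0.91), the RNA exosome subunit exosc1 (0.80) and the DNA glycosylase mbd4 (0.80). The same was seen for neuropeptide B, npb (0.83), and the clock gene per1 (0.33, from 27.9 ± 2.99 to 34.4 ± 2.47 in wild type and from 26.2 ± 2.99 to 33.9 ± 1.59 in the knockout). The symbol npb belongs to 2 genes of the table, and the value is that of gene 105354556. LOC101156361 and LOC111947176 rose by 1.90 and 1.32. The creatine synthesis gene gatm changed by -1.45, from 24.0 ± 5.97 to 8.40 ± 3.30 in wild type and from 25.2 ± 7.79 to 8.78 ± 3.39 in the knockout. Other falls were those of cyp26b1 (-1.56), tmem130 (-1.31), isyna1, which makes inositol phosphate (-0.92), the phosphatidylinositol transfer protein pitpnb (-0.88), fech (-0.79), the connective tissue growth factor ctgf (-0.72), the cystathionine γ-lyase cth (-0.71), pprc1 (-0.68), dbh, which makes noradrenaline (-0.39), and lonrf1 (-0.42). LOC101155766 and LOC101170847 changed by -2.33 and -1.68. The responses of gnrh1 (0.43, adjusted p = 0.0847), per2 (-0.31, adjusted p = 0.0981), dio2 (0.67, adjusted p = 0.230) and dio3 (-0.24, adjusted p = 0.231) did not pass. Without short-day wild-type replicate 1 gnrh1 did (adjusted p = 0.0174, with 0.0174 to 0.156 over all alternatives).

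Over both genotypes 562 genes passed, 231 higher and 331 lower under long days, and 3425 reached an unadjusted p under 0.05. Among those with a symbol, f13a1, fshb, lhb, cga, cyp19b, gltp, klhl24, map3k19, exosc1, mbd4, mcm7, cdk1, s100b, dhcr7, pprc1, cth, fech, pitpnb, tmem130, gatm and cyp26b1 passed with each library left out and under every other setting tried. The call of ctgf was lost without short-day wild-type replicate 2, that of hspd1 without long-day knockout replicate 14, and those of isyna1, npb, per1, dbh, lonrf1, cat, nsdhl, npas4, kif23, tpx2, chac1, psmb1, psmb3 and psmd6 each without 4 or more libraries. The count was 306, 281 and 335 without short-day wild-type replicates 1, 2 and 3, 334 without short-day knockout replicate 4, 367 and 273 without long-day wild-type replicates 13 and 15, and 305 and 214 without long-day knockout replicates 13 and 14.

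For the pooled photoperiod comparison 8 lists had a call with the preset correlation and 0 with an estimated one. Of 34 cell cycle genes 5 rose, among them mcm7 (0.61), cdk1 (0.50), tpx2 (0.60) and the cytokinesis motor kif23 (0.71), 0 fell, and 10 rose when adjusted over the list alone (adjusted p = 2.92e-05 by camera, adjusted p = 0.235 with an estimated correlation). In the gonadotropic axis 4 of 14 rose and 6 when adjusted over the list alone, gnrh1 and pgr being the additional members (adjusted p = 0.000208, adjusted p = 0.235 with an estimated correlation). In the pituitary hormone list 3 of 8 rose by either count (adjusted p = 0.00197, adjusted p = 0.235 with an estimated correlation). Proteasome genes were lower in 27 of 31 members, 3 fell (psmb1 -0.17, psmb3 -0.19, psmd6 -0.22) and 4 when adjusted over the list alone (adjusted p = 3.62e-05, adjusted p = 0.235 with an estimated correlation). All 12 immediate early genes were lower, 1 fell, npas4 (-0.87), and 2 when adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.563 with an estimated correlation). Of 21 cholesterol synthesis genes 2 fell by either count, the sterol dehydrogenase nsdhl (-0.64) and dhcr7 (-0.45; adjusted p = 0.0299, adjusted p = 0.850 with an estimated correlation). This list lost its call without short-day wild-type replicates 1, 2 (adjusted p = 0.0874 and 0.0895), short-day knockout replicate 3 (adjusted p = 0.193), long-day wild-type replicate 14 (adjusted p = 0.0508) or long-day knockout replicate 16 (adjusted p = 0.0697). Ribosomal protein genes were higher in 57 of 67 members with no member passing by either count (median 0.04, adjusted p = 0.00794, adjusted p = 0.976 with an estimated correlation). The adjusted p was 0.135 without short-day wild-type replicate 3, the library with high interferon genes, 0.209 without long-day knockout replicate 16, and 0.851 with the opposite direction without long-day wild-type replicate 13. Oxidative phosphorylation genes were higher in 32 of 49 members with none passing by either count (median 0.04, adjusted p = 0.0459, adjusted p = 0.916 with an estimated correlation). That call was lost without short-day wild-type replicate 2 or 3 (adjusted p = 0.150 and 0.104), short-day knockout replicate 1 or 4 (0.0552 and 0.0791), long-day wild-type replicate 13 or 14 (0.543 and 0.0587), or long-day knockout replicate 13 or 16 (0.0511 and 0.126). Without a call for their lists, hspd1 (-0.26) and chac1 (-0.34) fell, and s100b (0.39) and cat (0.38) rose.

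The genotype comparison under short days shows how the knockout differed from wild type before the move to long days. LOC111946846 had a mean of 184 ± 29.3 TPM in the knockout and was listed at 0 in all 6 wild-type libraries of both photoperiods, so no fold is given. LOC101160296 was higher in the knockout at 125 ± 57.1 against 0.690 ± 0.195 TPM (adjusted p = 0.0407). Of genes with a symbol, c20h8orf59 (gene 101167830) was the one with the largest increase, from 5.33 ± 0.240 in wild type to 41.3 ± 4.77 in the knockout (2.73, SE 0.21, adjusted p = 0.000284). The ankyrin-repeat gene sowahc (gene 101163369) followed, from 25.6 ± 0.972 to 121 ± 31.7 (2.16, SE 0.21, adjusted p = 0.00121). Also higher in the knockout were c23h12orf45 (8.86 ± 0.824 to 18.5 ± 1.55), ramp1, a partner of the CGRP receptor (13.6 ± 1.41 to 27.2 ± 3.84), tram1, of protein translocation into the ER (17.9 ± 2.75 to 33.6 ± 2.01), and cdk2ap2 (11.1 ± 0.932 to 18.6 ± 2.58). The same held for the synaptic organiser cbln2 (53.6 ± 5.25 to 82.9 ± 1.48), the mitochondrial pyruvate carrier subunit mpc2 (91.0 ± 8.83 to 134 ± 18.4), pdk3, a kinase of pyruvate dehydrogenase (43.3 ± 1.3 to 62.4 ± 1.24), and rpf2, of ribosome biogenesis (16.8 ± 1.11 to 23.9 ± 0.749).

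Lower in the knockout under short days was arf4 (gene 101161881), a small GTPase of the Golgi, at 5.94 ± 0.992 against 54.0 ± 23.1 TPM in wild type (-2.90, SE 0.36, adjusted p = 0.00735). The fatty acid elongation gene hacd1 went from 38.7 ± 4.40 in wild type to 18.7 ± 1.45 and the kinase prkx from 27.3 ± 2.85 to 12.7 ± 1.25. The phosphatidate phosphatase lpin2 went from 8.91 ± 0.266 to 3.52 ± 0.200, gpr143 from 6.92 ± 1.08 to 2.67 ± 0.643, and c21h2orf49 from 20.5 ± 1.70 to 8.42 ± 2.23. The calcium-binding protein gene cabp5 went from 50.5 ± 9.44 to 19.98 ± 5.85, tatdn2 from 4.13 ± 1.07 to 0.953 ± 0.205, armh1 from 14 ± 1.86 to 6.93 ± 1.92, and ndufv3, of respiratory complex I, from 14.9 ± 0.315 to 7.80 ± 2.46. The orexin gene hcrt, a hypothalamic neuropeptide, went from 13.8 ± 3.09 to 7.51 ± 0.835 (adjusted p = 0.0492). LOC101170320 and LOC105355818 went from 42.5 ± 7.22 and 18.9 ± 4.49 to 2.57 ± 1.33 and 2.72 ± 2.03. None of the reproductive, thyroid and clock genes fixed in advance passed under short days. Of these fshb differed by 1.25 (adjusted p = 0.197), lhb by 0.72 (adjusted p = 0.275), cga by -0.33, cyp19b by 0.21, gnrh1 by 0.33, dio2 by -0.18 and dio3 by -0.41, and for per2 the adjusted p was 0.995. The short-day wild-type group includes replicate 3, with fshb at 31.4 TPM, and without it the difference in fshb was 0.62 (adjusted p = 0.0517, with 0.0517 to 0.354 over all alternatives).

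Under short days 121 genes passed, 53 higher and 68 lower in the knockout, and 2398 reached an unadjusted p under 0.05. With median-ratio scaling 131 passed, 71 higher and 60 lower. Calls for LOC111946846, c20h8orf59, sowahc, c23h12orf45, tram1, c21h2orf49 and arf4 held with each library left out, those of hacd1 and gpr143 were lost without wild-type replicates 2 and 3 respectively, and every other named gene lost its call without at least 1 library. The count was 56, 33 and 27 without wild-type replicates 1, 2 and 3, and 61 without knockout replicate 3. With the preset correlation 5 of 27 lists had a call, and 0 with an estimated one. Immediate early genes were higher in the knockout in 10 of 12 members, with a median of 0.50, 0 passing over all genes and 7 rising when adjusted over the list alone, among them npas4, egr1, fosb and ier2 (adjusted p = 9.95e-07 by camera, adjusted p = 0.501 with an estimated correlation). Ribosomal protein genes were higher in 62 of 67 members, with a median of 0.12 and none passing by either count (adjusted p = 1.48e-11, adjusted p = 0.764 with an estimated correlation). Proteasome genes were higher in 22 of 31 members with none passing by either count (median 0.05, 0.0952 with median-ratio scaling, adjusted p = 0.0210, adjusted p = 0.764 with an estimated correlation), and without wild-type replicates 1 or 2 or knockout replicate 3 the adjusted p was 0.0644, 0.0980 and 0.0657. Of 6 genes of glycolysis and glucose use 4 were higher, none passed over all genes, and taldo1 and gapdh rose when adjusted over the list alone (adjusted p = 0.0367, adjusted p = 0.501 with an estimated correlation). Without wild-type replicate 2 or knockout replicates 3 or 4 that list's adjusted p was 0.184, 0.129 and 0.162. Interferon and antiviral genes were lower in the knockout in all 8 members, with none passing by either count (median -1.02, adjusted p = 0.0367, adjusted p = 0.764 with an estimated correlation). Their adjusted p was 0.485 without wild-type replicate 3, the library with rsad2 at 287 TPM, and 0.108, 0.0595 and 0.0786 without knockout replicates 1, 3 and 4.

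Under long days the knockout again had LOC111946846, at 314 ± 60.7 TPM, which wild type listed at 0. LOC101167112 stood at 69.5 ± 3.94 against 2.21 ± 0.327 TPM (4.46, SE 0.37, adjusted p = 0.000460). The autophagosome transport gene fyco1 was higher in the knockout, at 66.6 ± 3.65 against 5.22 ± 0.833 (3.45, SE 0.57, adjusted p = 0.0262). So were c20h8orf59, at 28.8 ± 8.31 against 5.99 ± 1.73 (2.09, SE 0.21, adjusted p = 0.00160), and sowahc, at 99.9 ± 29.6 against 26.5 ± 2.03 (1.84, SE 0.21, adjusted p = 0.00333). Other genes higher in the knockout were ubxn6, a cofactor of the p97 ATPase (43.4 ± 3.03 in wild type, 135 ± 13.5 in the knockout), the phosphatase-domain gene ptpdc1 (14.7 ± 1.40, 46.7 ± 2.44), tmem45a (3.95 ± 0.901, 18.2 ± 2.47) and uap1, which makes UDP-N-acetylglucosamine (7.21 ± 0.821, 19.7 ± 2.15). So were the HDL receptor scarb1 (6.44 ± 0.332, 16.4 ± 2.74), the ciliary BBSome gene bbs2 (22.6 ± 3.08, 49.5 ± 11.1), cdk2ap2 (9.11 ± 0.895, 19.7 ± 2.62) and the complex I subunit ndufs1 (5.91 ± 0.946, 13 ± 3.02).

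As under short days, arf4 was lower in the knockout under long days, at 9.67 ± 3.11 against 59.1 ± 26.8 TPM (-2.44, SE 0.36, adjusted p = 0.0126), and so was hacd1, at 23.3 ± 4.66 against 40.4 ± 4.19 (-0.78, SE 0.14, adjusted p = 0.0363). The N-terminal acetyltransferase naa50 went from 40.9 ± 3.15 in wild type to 24.8 ± 2.12 and the RNA-binding lsm6 from 163 ± 11.9 to 105 ± 11.3. The glutathione-degrading chac1 went from 547 ± 56.1 to 366 ± 17.7, ap3s2, of the AP-3 adaptor, from 68.1 ± 2.14 to 40.5 ± 2.06, and aig1 from 64.8 ± 0.738 to 39.7 ± 2.05. Also lower were arfrp1, an ARF-related GTPase (31.2 ± 1.96 to 19.7 ± 1.2), the lipid kinase pik3c2b (52.9 ± 6.18 to 33.9 ± 0.845), hgfac (4.18 ± 0.886 to 0.860 ± 0.0173) and ccdc189 (1.81 ± 0.0608 to 0.0767 ± 0.133). LOC111949218 went from 19.7 ± 3.11 to a level listed at 0 in all 3 knockout libraries, and LOC101171477 from 15.8 ± 1.83 to 0.320 ± 0.187. Neither fshb (-0.66, adjusted p = 0.567) nor lhb (0.78, adjusted p = 0.256) passed between genotypes under long days. The same fshb difference passed in a fit to the 2 long-day groups alone (adjusted p = 0.0198) and with short-day wild-type replicate 3 left out of the shared spread (adjusted p = 0.0131), with adjusted p up to 0.750 over all alternatives. For cga, cyp19b, gnrh1, dio2, dio3 and per2 the adjusted p ran from 0.484 to 0.981.

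**Figure D4:**
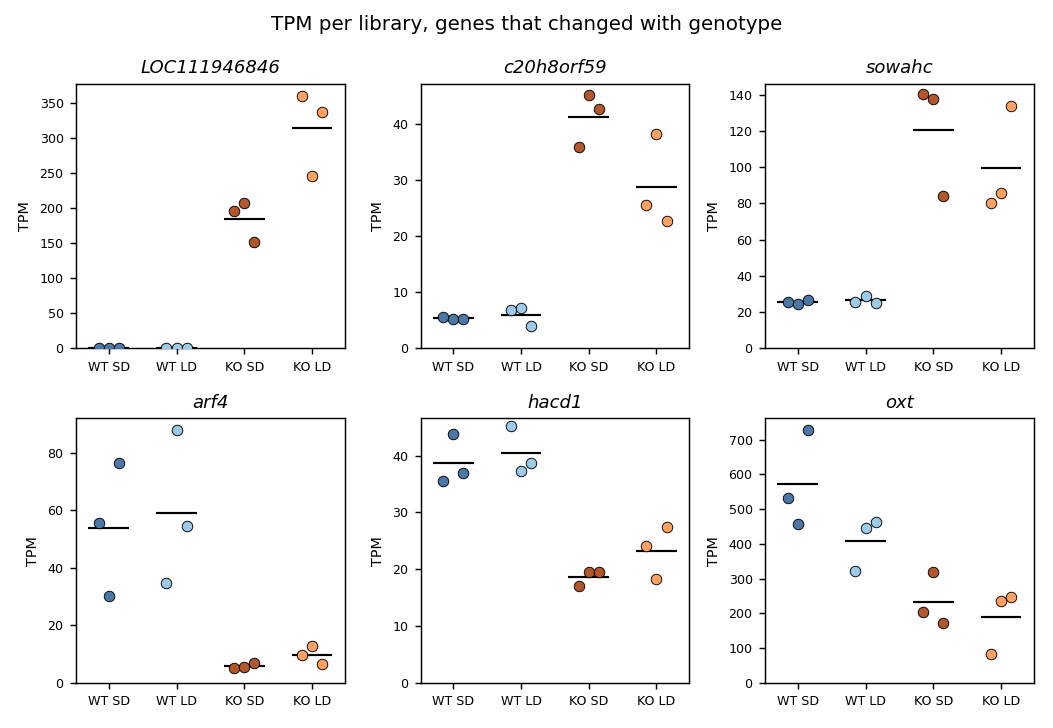
TPM of 6 genes that changed with genotype, in each library (points) with the group mean (line), in wild type (WT) and phod1 knockout (KO) under short days (SD) and long days (LD), n = 3 libraries per group. LOC111946846 is listed at 0 in all 6 wild-type libraries and has means of 184 and 314 TPM in the knockout, and arf4 lies lower in all 6 knockout libraries than in any wild-type library.

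Under long days 117 genes passed, 86 higher and 31 lower in the knockout, and 2051 reached an unadjusted p under 0.05. With median-ratio scaling 107 passed, 63 higher and 44 lower. Array weights gave 383, 264 higher and 119 lower, and a fit without a trend in the prior variance gave 72. Calls for LOC111946846, LOC101167112, c20h8orf59, sowahc, ptpdc1, uap1, scarb1, cdk2ap2 and naa50 held with each library left out, that of lsm6 was lost without knockout replicate 14, and the other named genes lost theirs without at least 1 library. The count was 51, 51 and 43 without wild-type replicates 13, 14 and 15, 43 and 57 without knockout replicates 14 and 16, and 77 when short-day wild-type replicate 3 was left out of the shared spread, an alternative chosen after the data were seen. With the preset correlation 4 of 27 lists had a call, and 0 with an estimated one. Cholesterol synthesis genes were lower in the knockout in 18 of 21 members, with a median of -0.30, 0 passing over all genes and 4 falling when adjusted over the list alone, mvd, tm7sf2, sc5d and dhcr7 (adjusted p = 2.02e-06 by camera, adjusted p = 0.656 with an estimated correlation). Immediate early genes were higher in 10 of 12 members, with a median of 0.46, 0 passing over all genes and 6 when adjusted over the list alone (adjusted p = 0.000377, adjusted p = 0.729 with an estimated correlation). Endothelial and pericyte genes were higher in 12 of 13 members, and the transcription factor sox18 and the tight junction gene cldn5 rose when adjusted over the list alone (median 0.31, adjusted p = 0.00123, adjusted p = 0.113 with an estimated correlation). Ribosomal protein genes, higher in the knockout under short days, were lower in 53 of 67 members under long days, with none passing by either count (median -0.05, -0.0905 with median-ratio scaling, adjusted p = 0.000532, adjusted p = 0.983 with an estimated correlation). Without knockout replicate 13 their adjusted p was 0.542, and without wild-type replicate 13 it was 0.0527 in the opposite direction.

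The genotype calls of the 2 photoperiods shared 16 genes higher in the knockout, against 0.25 expected for independent lists, among them LOC111946846, LOC101167112, c20h8orf59, sowahc, cdk2ap2, tram1 and the phospholipid transfer protein pltp. They shared 10 lower ones, against 0.116 expected, among them arf4, hacd1, naa50 and the deubiquitinase usp12. No gene passed in opposite directions. Of the 121 short-day calls 105 had the same sign under long days, and of the 117 long-day calls 97 had the same sign under short days. Across genes the genotype differences correlated with Pearson's r = 0.357 and Spearman's rho = 0.242.

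Over both photoperiods, with 6 libraries against 6, the isotocin precursor gene, given as oxt (gene 101161643), was lower in the knockout, at 232 ± 77.6 and 188 ± 92.2 TPM under short and long days against 572 ± 140.1 and 409 ± 77.2 in wild type (-1.29, SE 0.27, adjusted p = 0.0308). The orexin gene hcrt was lower as well (-0.50, SE 0.11, adjusted p = 0.0360). Further genes lower in the knockout were arf4 (-2.67), smyd3, a lysine methyltransferase (-1.48), pglyrp2, of the peptidoglycan recognition family (-1.35), hgfac (-1.23), ccdc189 (-1.23), hacd1 (-0.90), c21h2orf49 (-0.85), prkx (-0.85), the peroxisome assembly gene pex2 (-0.84) and s100b (-0.33), with LOC111949218 at -3.20 and LOC110013896 at -2.53. Higher in the knockout were c20h8orf59 (2.41), sowahc (2.00), tmem45a (1.76), ubqln1 (1.26), and efemp2 (1.05). Also higher were scarb1 (1.02), uap1 (0.97), rprm (0.96), ndufs1 (0.73), the pentose phosphate gene taldo1 (0.65), the transcription factor cebpd (0.67) and pou1f1, a transcription factor of pituitary cells (0.46), with LOC101167112 at 4.13. Of 19 heat shock and ER stress genes, xbp1 was higher (0.33), edem1 (-0.80), chac1 (-0.53) and ddit3 (-0.45) were lower and 15 did not pass, and the list had no call (adjusted p = 0.628 by camera, adjusted p = 0.927 with an estimated correlation). The difference in lhb was 0.75 (adjusted p = 0.0634), and it passed without long-day knockout replicate 14, at 0.92 (adjusted p = 0.00963, with 0.00963 to 0.273 over all alternatives). That in fshb was 0.29 (adjusted p = 0.683), which became -0.02 without short-day wild-type replicate 3, where fshb stood at 31.4 TPM. For cga, cyp19b, gnrh1, dio2, dio3 and per2 the adjusted p ran from 0.299 to 0.959.

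Over both photoperiods 437 genes passed, 236 higher and 201 lower in the knockout, and 2841 reached an unadjusted p under 0.05. Among those with a symbol, c20h8orf59, sowahc, ier2, prkx, hacd1 and arf4 passed with each library left out and under every other setting tried. The call of oxt was lost without any 1 of 7 libraries, namely short-day wild-type replicates 1 and 3, short-day knockout replicates 1 and 4 and the 3 long-day wild-type libraries, with adjusted p up to 0.0750. That of hcrt was lost without any 1 of 10 libraries and that of edem1 without short-day wild-type replicate 3 or long-day wild-type replicate 13. The count was 230, 263 and 208 without short-day wild-type replicates 1, 2 and 3, 263, 279 and 209 without long-day wild-type replicates 13, 14 and 15, and 245 and 280 without long-day knockout replicates 14 and 16. With the preset correlation 3 of 27 lists had a call, each held with every library left out, and 0 had one with an estimated correlation. Of 12 immediate early genes 3 rose, the immediate early response gene ier2 (1.07), the neuronal activity gene npas4 (0.84) and the phosphatase dusp5 (0.60), and 10 rose when adjusted over the list alone (adjusted p = 7.37e-07 by camera, adjusted p = 0.539 with an estimated correlation). Of 21 cholesterol synthesis genes 18 were lower, 1 fell, the sterol desaturase sc5d (-0.51), and 5 fell when adjusted over the list alone (adjusted p = 0.00105, adjusted p = 0.568 with an estimated correlation). Of 13 endothelial and pericyte genes 11 were higher, none passed over all genes, and 6 rose when adjusted over the list alone, among them sox17, sox18, tie1 and cldn5 (adjusted p = 0.00249, adjusted p = 0.132 with an estimated correlation).

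The other 14 tested lists had no call in any of the 7 comparisons. For catecholamine and serotonin neurons the smallest adjusted p was 0.0654, over both genotypes, where 7 of 8 genes were lower under long days and dbh fell. For the photoperiodic thyroid axis it was 0.139, under short days, where all 8 genes were lower in the knockout and none passed. For glucocorticoid-responsive genes it was 0.208 (genotype, both photoperiods), for hypothalamic neuropeptides 0.317 (genotype, long days), for lymphocyte genes 0.336 (photoperiod, knockout), and for antigen presentation 0.551 (genotype, short days). In the wild-type photoperiod comparison the smallest adjusted p was 0.266 for nuclear RNA and splicing genes, 0.277 for general neuronal genes, 0.331 for tanycyte and ependymal genes and 0.580 for oligodendrocyte and myelin genes. In the interaction it was 0.356 for DNA repair and light-response genes, 0.375 for meningeal and fibroblast genes, 0.569 for the core clock and 0.569 for fatty acid synthesis and lipid transport. In all 39 list results with a call the test, the median and the mean had the same sign, and in 44 of the 150 without a call they did not. Another 10 lists had fewer than 5 tested members and were not tested: non-visual opsins (2 members), microglia and macrophages (3), erythroid cells (0), skeletal muscle (1), photoreceptors (2), lens (4), oestrogen-induced liver proteins (1), sex determination (4), complement and acute phase (3) and the mitochondrial genome (0). Of the genes fixed in advance, prl had too low a TPM to be tested, and tshb, gh1, kiss1, kiss2, opn5, eya3, cry1a and nr1d1 matched no symbol of the table.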

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

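The interaction test behind the differences in the first paragraph below was planned, while the tests of explanations, and the limits set for the counts over other splits of the samples, were written after the results they bear on were seen.

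Results that differed between the genotypes' photoperiod responses by the interaction test were 1 gene and 3 lists. LOC110015663 had a difference of 3.29 on the log2 scale (knockout minus wild type). The list medians were -0.18 for ribosomal proteins, -0.24 for cholesterol synthesis and -0.0464 for the proteasome (-0.128 with median-ratio scaling), and none of these lists passed with an estimated correlation. Among 100 splits of the genotype labels within photoperiods, the real one included, 33 gave at least 1 gene by the interaction test and 62 gave at least 3 lists. The highest other split gave 437 genes, since exchanging the genotype labels in 1 photoperiod turns the interaction into the pooled genotype difference, and the most lists in another split was 10. Other splits can carry part of that genotype difference too, so these counts give no clean level for chance. Chance is therefore not excluded for either, and the splits cannot decide it.

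Genotype calls lay near one another along the chromosomes. Under short days 59 of 121 calls had another call 6 to 30 tested genes away, against a mean of 33.4 for random placement (permutation p = 0.00012), and under long days 61 of 117 against 31.4 (permutation p = 1e-05, the smallest the permutations can give). Reads shared between adjacent copies of a gene act on closer neighbours, and the lower of these ratios to random placement, 1.77, argues against them as the whole cause. The 562 pooled photoperiod calls had a ratio of 0.974 and the 437 pooled genotype calls 1.16, both held near 1 by their number, and at an equal number of 121 genes with the smallest p the ratios were 0.958 for pooled photoperiod (permutation p = 0.61) and 2.1 for pooled genotype (permutation p = 1e-05), so genomic segments that differ between the fish of the genotypes may account for the pattern. Loss of phod1 acting on genes wherever they lie is argued against as the whole cause by the ratio of 1.96 within 30 tested genes under long days, while the 55 short-day and 45 long-day calls with no other call within 30 tested genes stay open to it.

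More genes were called by photoperiod in the knockout (321) than in wild type (35), while with array weights the counts were 462 and 292. The adjusted threshold, which fell at different unadjusted p in the comparisons, stays open as a cause, since at the largest p called in wild type, 9.15e-05, the knockout had 99 genes to 35, but at an unadjusted p under 0.05 the counts were 2898 and 2117. The short-day wild-type library with high interferon genes stays open as a cause. Without it wild type had 23 calls and the knockout 212, but the wild-type comparison then had fewer libraries than that of the knockout. Wild-type counts ran from 10 to 33 with each wild-type library left out in turn, so these counts cannot decide it. Over the 562 pooled photoperiod calls the median response was 0.43 in the knockout and 0.30 in wild type, with a median difference of 0.08 that ran from 0.06 to 0.11 with each library left out. Of 100 splits of the genotype labels 6 gave a median difference as far from 0, the highest other being 0.0992, so larger responses in the knockout stay open as an explanation that may hold. These splits too can carry part of the genotype difference, so 6 of 100 is no clean level for chance.

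Short-day wild-type replicate 3 held 38 genes more than 2 log2 units above every other library, among them rsad2, cmpk2, dhx58, irf9, helz2, ifi35, cxcl13 and znfx1, while each of the other libraries held 0 to 5 such genes. A rise of lymphocytes or microglia of that size is argued against, with median deviations from the group of 0.202 for lymphocyte genes and 0.232 for 3 microglial genes, against 2.82 for interferon and antiviral genes. In the other 11 libraries these deviations ran from -0.331 to 0.444 for lymphocyte genes and from -0.338 to 0.277 for microglial genes. A smaller share of leukocytes stays open, since the leukocyte gene ptprc stood at 9.75 TPM, against 3.49 to 6.78 in the other 11 libraries. Antigen presentation genes deviated by 0.681, but that list shares tap1 with the interferon and antiviral list, so its rise is not separate evidence of leukocytes. A knockout library under a wild-type label is argued against too, since at 82.7% of the 208 genotype calls made without it the library lay nearer the other short-day wild-type libraries. No biological explanation, such as an infection of that fish, was tested.

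Other splits of the samples were counted for the remaining results. For comparisons of 3 against 3 there are only 10 splits, too few for a share under 0.05. By gene count the real split stood at 35 against a highest other of 3 for photoperiod in wild type, 321 against 2 in the knockout, 121 against 1 for genotype under short days and 117 against 2 under long days, each with 1 split as large, the real one. By list count the real values were 8 against 7, 8 against 7, 5 against 9 and 4 against 8, with 1, 1, 6 and 7 splits as large. Over both photoperiods 437 genotype calls stood against at most 12 in the other splits, and over both genotypes 562 photoperiod calls against at most 13. In each, 1 of 100 splits was as large, the smallest share these splits can give, so chance is argued against for these counts. Chance is argued against for the correlation of the photoperiod responses in the main setting as well, at 0.179 against at most 0.125, again with 1 of 100. With a pseudocount of 0.1 that correlation was 0.114, and no splits were drawn at that setting. Chance cannot be excluded for the number of lists over both photoperiods by genotype (3, with 67 of 100 splits as large and a highest other of 10) or over both genotypes by photoperiod (8, with 9 of 100 and a highest other of 9).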

How the results depend on the processing

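The alternatives were planned, except that leaving short-day wild-type replicate 3 out of comparisons it does not belong to was chosen after the data were seen. Each group has 3 libraries, the table keeps no depth, and adding 1 before the logarithm shrinks changes of genes with few TPM, so calls near the threshold move with the number of libraries and the estimate of the spread. Of the 184 calls of named genes 51 held under every alternative, 39 of them for genes with a symbol. With 1 library left out, 1070 of 1635 values for named calls kept the call and 565 lost it, and under the other alternatives 1205 of 1460 kept it and 255 lost it, with no change of direction. Median-ratio scaling moved the calls lower under long days from 23 to 13 in wild type and from 119 to 182 in the knockout. It also moved list medians, from 0.0510 to 0.0986 for pituitary hormones, 0.0371 to 0.0882 for oxidative phosphorylation and 0.0192 to 0.0700 for radial glia by photoperiod in wild type, from -0.0505 to -0.0813 for ribosomal proteins by photoperiod in the knockout, from 0.0522 to 0.0952 for the proteasome by genotype under short days, from -0.0518 to -0.0905 for ribosomal proteins by genotype under long days, and from -0.0464 to -0.128 for the proteasome by interaction. Removal of the 20 most abundant genes moved the pituitary hormone median to 0.0274. Where a value below differs, the cause was not tested, apart from a smaller number of libraries where libraries are left out.

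By setting, a pseudocount of 0.1 gave 0 interaction genes by limma (1419 at an unadjusted p under 0.05) and a correlation of the photoperiod responses of 0.114, against 1 and 0.179 in the main results. Testing all genes with a TPM above 0 gave 6 and 0.151, and a minimum of 5 TPM gave 0 (1191 at an unadjusted p under 0.05) and 0.206, with different genes tested by construction. Without a trend in the prior variance there were 186 photoperiod calls in the knockout, 72 genotype calls under long days and 5 interaction genes. Array weights, which ran from 0.524 for long-day wild-type replicate 13 to 2.77 for long-day wild-type replicate 15, gave 292 photoperiod calls in wild type, 383 genotype calls under long days, 9 interaction genes, and 719 genotype and 1068 photoperiod calls over both strata. With the 2 compared groups alone there were 1 and 61 photoperiod calls in wild type and the knockout, 74 genotype calls under short days and 139 under long days, the last above the 117 of the main results, with fewer libraries for the spread in each by construction. Without short-day wild-type replicate 3, outside the comparison, there were 212 photoperiod calls in the knockout and 77 genotype calls under long days. With an estimated correlation 0 of the 39 list calls by camera remained.

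The number in the sample titles, entered as a replicate block, gave 6 genotype calls under short days, 6 under long days, 30 over both and 0 interaction genes by limma (1253 at an unadjusted p under 0.05). Numbers 1 and 3 under short days and 13 and 14 under long days occur in both genotypes, and after removal of the group means the libraries with the same number correlated at 0.0817, 0.0881, -0.0478 and -0.00492 across genes. These few values show no strong pairing but cannot exclude one, since libraries with different numbers were not compared. The remaining numbers occur in 1 genotype only, so the block compares genotypes within the shared numbers alone. It also leaves fewer residual degrees of freedom by construction. In this block fit the interaction of lhb was -0.24 and the pooled genotype differences of gnrh1 and cga were -0.0509 and 0.0318, opposite in sign to the main results.

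With 1 library left out the counts ran from 10 to 33 (photoperiod, wild type), 81 to 216 (photoperiod, knockout), 27 to 95 (genotype, short days), 43 to 91 (genotype, long days), 0 to 6 (interaction), 208 to 380 (genotype, both) and 214 to 520 (photoperiod, both), and the correlation from 0.140 to 0.193. Of the values of named genes with no call, 6 of 468 passed with 1 library left out and 2 of 412 under the other alternatives. These were fshb by interaction (0.0177) and by genotype under long days (0.0131 and 0.0198), lhb by pooled genotype (0.00963), gnrh1 by photoperiod in wild type (0.0363) and over both genotypes (0.0174), and sbds (0.0440) and gpat3 (0.0486) by interaction, as adjusted p. Others, 24 and 10 values, changed sign. In log2 units, genotype under short days ran from -0.0729 to 0.0882 for per2 and from -0.58 to 0.34 for dio2. Genotype under long days ran from -0.0693 to 0.34 for cga, -0.13 to 0.0990 for dio2 and -0.20 to 0.0826 for dio3. Pooled genotype ran from -0.0223 to 0.46 for fshb, -0.0522 to 0.16 for gnrh1, -0.0626 to 0.0941 for cyp19b, -0.23 to 0.00231 for cga and -0.31 to 0.15 for dio2. Photoperiod in the knockout ran from -0.21 to 0.0731 for dio3, and the interaction from -0.39 to 0.53 for dio2 and from -0.18 to 0.41 for lhb. The adjusted p of ribosomal proteins ran from 7.20e-08 to 0.851 for photoperiod over both genotypes and from 2.97e-15 to 0.542 for genotype under long days, with the direction reversed without long-day wild-type replicate 13 in both (0.851 and 0.0527). Median-ratio scaling reversed per2 under short days (0.0379) and the interaction of lhb (-0.0151), and array weights reversed cga (-0.0688), dio2 (0.0383) and dio3 (0.10) under long days, the interaction of lhb (-0.0999) and the pooled genotype difference of cyp19b (-0.0607).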

Other observations

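The genes in the first 2 paragraphs of this part were picked, and the ribosome biogenesis test was chosen, after their values were seen. Libraries of the knockout differed among themselves in a run of neighbouring genes. The genes uap1, ubxn6, tmem45a and fyco1 lie on 1 chromosome in this order in ASM223467v1, with 0 tested genes between uap1 and ubxn6 and 56 between ubxn6 and tmem45a. In short-day knockout replicate 1, fyco1 stood at 5.45 TPM, ubxn6 at 39.4, uap1 at 9.40 and tmem45a at 5.22, against short-day wild-type means of 5.55, 40.3, 8.27 and 3.34. In short-day knockout replicate 3 the same genes stood at 33.5, 80.3, 13.4 and 12.1 TPM, and in replicate 4 at 55.6, 105.6, 17.7 and 23.5. The long-day knockout libraries stood at 63.8 to 70.7 TPM for fyco1, 124 to 150.3 for ubxn6 and 18.3 to 22.2 for uap1, above replicate 4, and at 15.8 to 20.8 for tmem45a, below it.

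Other genes switched between levels within the knockout. LOC101160296 stood between 78.1 and 191 TPM in 5 knockout libraries and at 0.57 in long-day knockout replicate 16, with 0.5 to 0.89 in the 6 wild-type libraries. LOC101170320 stood at 40.7 TPM in long-day knockout replicate 13 and at 1.54 to 4.08 in the other knockout libraries, against 31.9 to 50.6 in wild type. LOC101171477 stood at 14.4 and 12.5 TPM in short-day knockout replicates 3 and 4, against 13 to 17.8 in wild type, and at 0.17 to 0.53 in the other knockout libraries. LOC111949218 stood at 9.1 and 7.45 TPM in short-day knockout replicates 1 and 4 and was listed at 0 in the other knockout libraries. The lysine methyltransferase gene smyd3 stood at 6.74 and 7.38 TPM in 1 knockout library of each photoperiod and at 1.80 to 2.24 in the other 4. A further run on 1 chromosome held pex2, pdk3, cbln2, tram1, naa50, hacd1, lpin2 and c20h8orf59, all called in a genotype comparison, with 28, 10, 18, 42, 78, 8 and 54 tested genes between them. Of these, pdk3, cbln2, tram1 and c20h8orf59 were higher in the knockout and pex2, naa50, hacd1 and lpin2 lower.

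A hypothesis tested after the ribosomal protein result was seen was that ribosome biogenesis genes may be lower as a group under long days. Over both genotypes the 86 tested genes of that list had a median change of -0.06 on the log2 scale, 2 rose and 0 fell. By camera the p was 0.0589 with the preset correlation and 0.326 with an estimated one, so the test did not decide it. In the knockout alone the median was -0.0592 (camera p = 0.00847, p = 0.183 with an estimated correlation), in wild type alone it was -0.0438 (camera p = 0.890, p = 0.941 with an estimated correlation), and the interaction had a median of 0.00211 (camera p = 0.0134, p = 0.208 with an estimated correlation), none adjusted for the number of contrasts. Over all tested genes the corresponding medians were 0.0290 in the knockout, -0.0455 in wild type and 0.0765 in the interaction.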
